A study of Homo sapiens with 12 samples.

How the data were processed

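RNA was measured in 12 libraries, a DCIS and an IDC lesion of each of 6 patients, prepared from total RNA with a column kit and the TruSeq RNA protocol, per the labels' protocols. The reads were placed on the human genome build hg19 (GRCh37), per the submitters' processing notes. The aligner, the counting tool and the gene annotation are not given in the sources used here, and no coordinates are printed.

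The authors deposited one table of normalized log2 values, with a group mean, a p-value of a test named EDGE and a signed fold for each gene, per the file headers. Its values were checked on the table itself. The sorted values of all 12 columns were identical (largest difference 0), which is quantile normalization, and the lowest steps above 0 were those of a mean over 12 libraries of log2(reads + 1). Quantile normalization gave genes of equal reads different values by their place in the table, so that up to 5034 genes of a library with 0 reads had a value above 0, at most 2.505. From that order the reads of low genes were recovered in each library. At 44769 of 57773 ranks (77.5%) the deposited value equalled the mean log2(reads + 1) of the recovered reads within 1e-06, up to a value of 7.26. Of these ranks 11608 held a value above 0, and only those test the recovery. The recovered reads gave a relative depth for each library, from 79 to 297 reads at one rank. This is not library size, and its order differed from that of the number of genes with reads. Where reads were recovered, the deposited fold was the ratio of the mean reads of the groups, not scaled for depth. Its size matched in 100% of 9825 genes, and its direction in 100% of those whose means differ. In 3032 rows the deposited fold was a division error. The full read counts cannot be recovered above a value of 7.26, so count tests were not run.

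Values were used as deposited. Each column summed to 40864788 after the logarithm was undone, and a gene was tested if its mean over the 12 libraries was at least 5.39, the value that stands for a CPM of 1 on that sum. XIST and Y-linked rows (473) were left out throughout. This left 15493 genes. Fixed plans had foreseen counts or linear units such as CPM. The log2 values needed no pseudocount, and the filter was carried over as described.

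IDC was compared with DCIS by limma 3.58.1 in R 4.3.3, with patient as a block and trended, robust empirical Bayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The labels give both lesions of each patient, which is where the pairing comes from. The correlation of the lesions of one patient averaged 0.432 (lowest 0.048). With 6 pairs there were 5 residual degrees of freedom. Simulated data with the real patient means and residual spread over 15493 genes were tested first. Between IDC and DCIS 29% of 100 genes changed 2-fold and 73% of 100 genes changed 4-fold were found, with 5 false calls. The simulated errors were normal and independent between genes, and each change was equal in all 6 pairs. Real genes varied together and real differences varied between pairs, so recovery in the real data may be lower.

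The 31 gene lists, drawn up before the data were examined, cover cell types, tumour programmes and signs of RNA quality. They were tested with camera (preset correlation 0.01, and an estimated correlation), with fry, and by a list score, the mean log2 value of the tested members, compared within patients by an exact two-sided sign-flip test. Of the list entries 8 were not found by name, and a list needed at least 5 tested members. The similarity of the lesions was tested over all 720 pairings. Genes are named by a rule set in advance. It takes up to 10 genes per direction that pass, go one way in at least 5 of 6 pairs and have a mean of at least 7.68 (a CPM of 5), filled up with the smallest unadjusted p where fewer pass. It adds up to 4 members of each list with the smallest unadjusted p, and 16 fixed genes. Some members that this rule takes are not reported here. Errors are SD between libraries or pairs, or SE of the fit, as stated, and log2 fold changes are IDC minus DCIS.

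Alternatives set before the data were examined were no replicate block, quantile normalization over the tested genes, no filter, a stricter filter at a CPM of 5, pseudocounts of 0.1 and 0.01, array weights, empirical Bayes with neither trend nor robust, a fold of at least 2 in addition, an estimated correlation, medians in place of means, the 1000 genes with the largest variance, Spearman correlation, and each pair left out. Cyclic loess, and the adipocyte or the luminal epithelial score as a covariate, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.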

Results

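Gene expression was measured by RNA sequencing in breast lesions of 6 patients. Each patient gave a ductal carcinoma in situ (DCIS), in which tumour cells stay within the duct, and an invasive ductal carcinoma (IDC), in which they have crossed into the surrounding tissue, so the 12 libraries form 6 pairs. The design asks which genes differ between the lesion types within a patient. The deposited table held 57773 gene rows of quantile normalized log2 values. Between 19578 and 24612 genes had at least 1 read in a library, with a mean of 22526 ± 1497 in DCIS and 21942 ± 1307 in IDC (SD, n = 6 each). Relative depth, read at one fixed rank of the table, ranged from 79 to 297 reads, a 3.76-fold span. Its means were 165.5 ± 69.3 in DCIS and 162 ± 75.5 in IDC (SD, n = 6 each). Depth was not matched within every pair. DCIS and IDC had 147 and 297 reads in replicate 6, 296 and 193 in replicate 1, and 127 and 128 in replicate 3.

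On average, the lesions of one patient resembled each other more than a DCIS and an IDC of different patients did. Over 15493 expressed genes, centred gene by gene, the Pearson correlation between the DCIS and the IDC of one patient averaged 0.432, with a range from 0.048 to 0.76. Between a DCIS and an IDC of different patients it averaged -0.138, with a highest value of 0.508, and between DCIS of different patients it reached 0.704. Among the IDC libraries, that of the same patient correlated best for 4 of 6 DCIS, and among the DCIS libraries, that of the same patient did so for 6 of 6 IDC. No other pairing of the 6 DCIS with the 6 IDC libraries reached the mean of the true pairing (exact permutation test over 720 pairings, one-sided p = 0.00139, the smallest these pairings can give). These correlations are across genes, which are not independent replicates. Differences between patients held 69.8% of the variance of the values and the mean difference between lesion types 5.4%. Patient means and a lesion difference hold a share of the variance even without any effect. That share was not taken off, so neither percentage measures an effect by itself.

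No single gene differed between IDC and DCIS after adjustment for the number of genes tested. Among genes higher in IDC in all 6 pairs were SUSD2, a membrane protein with a sushi domain, AREG, a ligand of the epidermal growth factor receptor, and WNT7B, a Wnt ligand. Among genes lower in IDC in all 6 pairs were MS4A7, a membrane protein of macrophages, ACADM, an enzyme of fatty acid oxidation, and IDH1, the cytosolic isocitrate dehydrogenase. In the limma fit with patient as a block, 0 of 15493 genes passed a Benjamini-Hochberg adjusted p of 0.05, and the lowest adjusted p was 0.774. At an unadjusted p under 0.05 there were 701 genes (4.52%), 377 higher and 324 lower in IDC, where an even spread of p gives 775. That count was 334 without replicate 1, 465 without replicate 4, 461 without replicate 5 and 1540 without replicate 6. In the fit without the patient block 0 genes passed and 125 had an unadjusted p under 0.05. All 6 pairs went one way in 468 genes (226 higher and 242 lower), where chance gives 3.125% of genes, or 484. The median gene had a 95% interval of 0.59 to either side of its log2 fold change.

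**Figure D1:**
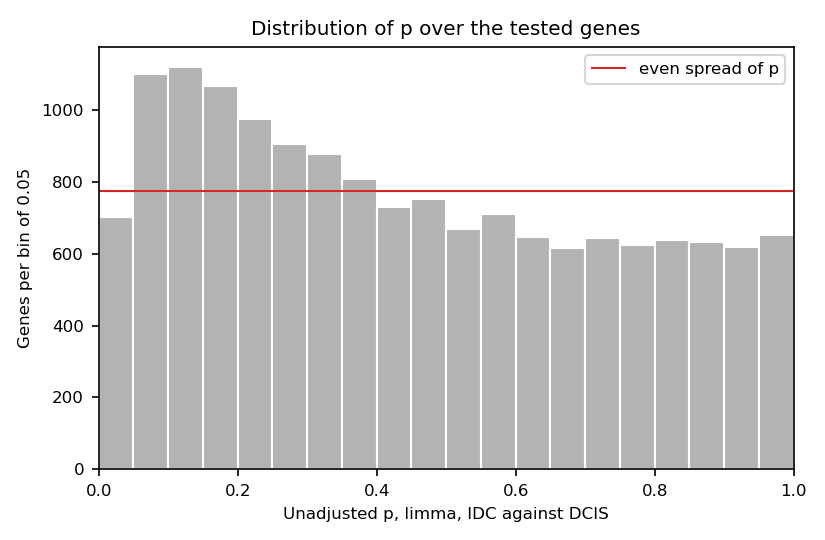
Number of genes (y axis) per bin of 0.05 of the unadjusted limma p for IDC against DCIS (x axis), over 15493 genes. The first bin holds 701 genes, under the 775 of an even spread (red line), and the bins that follow it, up to a p of 0.4, lie above that line.

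Genes with the smallest unadjusted p, given here as values that did not pass, were chosen for one direction in at least 5 of 6 pairs. SUSD2 was 0.89 ± 0.17 higher in IDC on the log2 scale (SE), from 10.43 ± 2.25 in DCIS to 11.32 ± 2.27 in IDC (SD, n = 6), and higher in 6 of 6 pairs, with one library far above the others in each lesion type. AREG was 1.36 ± 0.29 higher, WNT7B 1.20 ± 0.28 higher, and SEMA4C, a semaphorin, 0.60 ± 0.14 higher, each in 6 of 6 pairs. EFS, ABTB2 and PLCH2 were also higher in 6 of 6 pairs, with log2 differences from 0.70 to 1.02, and EVPL, encoding the cornified-envelope protein envoplakin, was 1.13 higher in 5 of 6. ATP6V1G2-DDX39B was 2.13 ± 0.35 higher, and is uncertain because this readthrough gene shares its sequence with the genes it joins. FAM83H-AS1 was 1.48 higher and is uncertain because the strand setting of the counting is not given in the sources used here. On the lower side, MS4A7 was -0.92 ± 0.22, ACADM -0.97 ± 0.25 and IDH1 -0.79 ± 0.20 on the log2 scale (SE), each lower in 6 of 6 pairs. SLC41A2, ALPK3, CD302, ZDHHC2, STRADB and PEX11A were lower in 6 of 6 pairs, with log2 differences from -1.40 to -0.52, and GLRX, glutaredoxin, was -0.86 in 5 of 6. The limma adjusted p was 0.774 for each of these 20 genes.

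Genes fixed in advance, which cover receptors, keratins, matrix and adhesion, did not pass either. BCL9, a co-activator of beta-catenin, was 9.60 ± 0.58 in DCIS and 10.58 ± 1.10 in IDC (SD, n = 6), a log2 difference of 0.98 ± 0.36 (SE) and 1.97-fold higher, with 5 of 6 pairs higher (limma adjusted p = 0.774). CTNNB1, beta-catenin itself, differed by 0.27 ± 0.22. MMP11, a stromal protease, had the widest difference of these genes at 2.16 ± 1.09, with 5 of 6 pairs higher. COL11A1 differed by 1.53 ± 0.99 with 3 of 6 pairs higher, and COL1A1, the main fibrillar collagen, by 1.21 ± 0.61 with 6 of 6 higher and one IDC library far below the others. MKI67, a marker of cycling cells, differed by 1.01 ± 0.46 in 5 of 6 pairs. ERBB2, a growth factor receptor, differed by 0.95 ± 0.47 in 4 of 6, and by -0.0064 with the luminal epithelial score as a covariate. The largest pair differences of the luminal score (3.01) and of the ERBB2 amplicon score (2.79) came from the same pair. That fit therefore cannot tell epithelial content from this pair. ESR1 and PGR, the oestrogen and progesterone receptors, differed by 0.29 ± 0.73 and -0.69 ± 0.53. The basal keratins KRT5 and KRT14 differed by -0.47 ± 0.53 and -0.39 ± 0.58, and turned to 0.11 and 0.28 with array weights. The epithelial genes CDH1 and EPCAM differed by 0.66 ± 0.40 and 0.78 ± 0.53. With the luminal epithelial score as a covariate they turned to -0.080 and -0.23, and CTNNB1 to -0.073. ACTA2, VIM and the leukocyte gene PTPRC differed by 0.05 ± 0.49, -0.32 ± 0.41 and -0.31 ± 0.43, with one IDC library far above the others for PTPRC. ESR1, KRT5, KRT14, ACTA2, VIM and PTPRC changed sign when single pairs were left out. Without one pair the log2 difference ranged from 0.47 to 1.41 for COL1A1 (lowest without replicate 4), from 0.78 to 2.15 for COL11A1 (without 4) and from 1.34 to 3.03 for MMP11 (without 1). It ranged from 0.43 to 1.20 for ERBB2, 0.60 to 1.35 for MKI67, 0.32 to 0.95 for CDH1, 0.27 to 1.11 for EPCAM and 0.097 to 0.43 for CTNNB1, each lowest without replicate 1, from -1.22 to -0.39 for PGR and from 0.67 to 1.26 for BCL9.

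**Figure D2:**
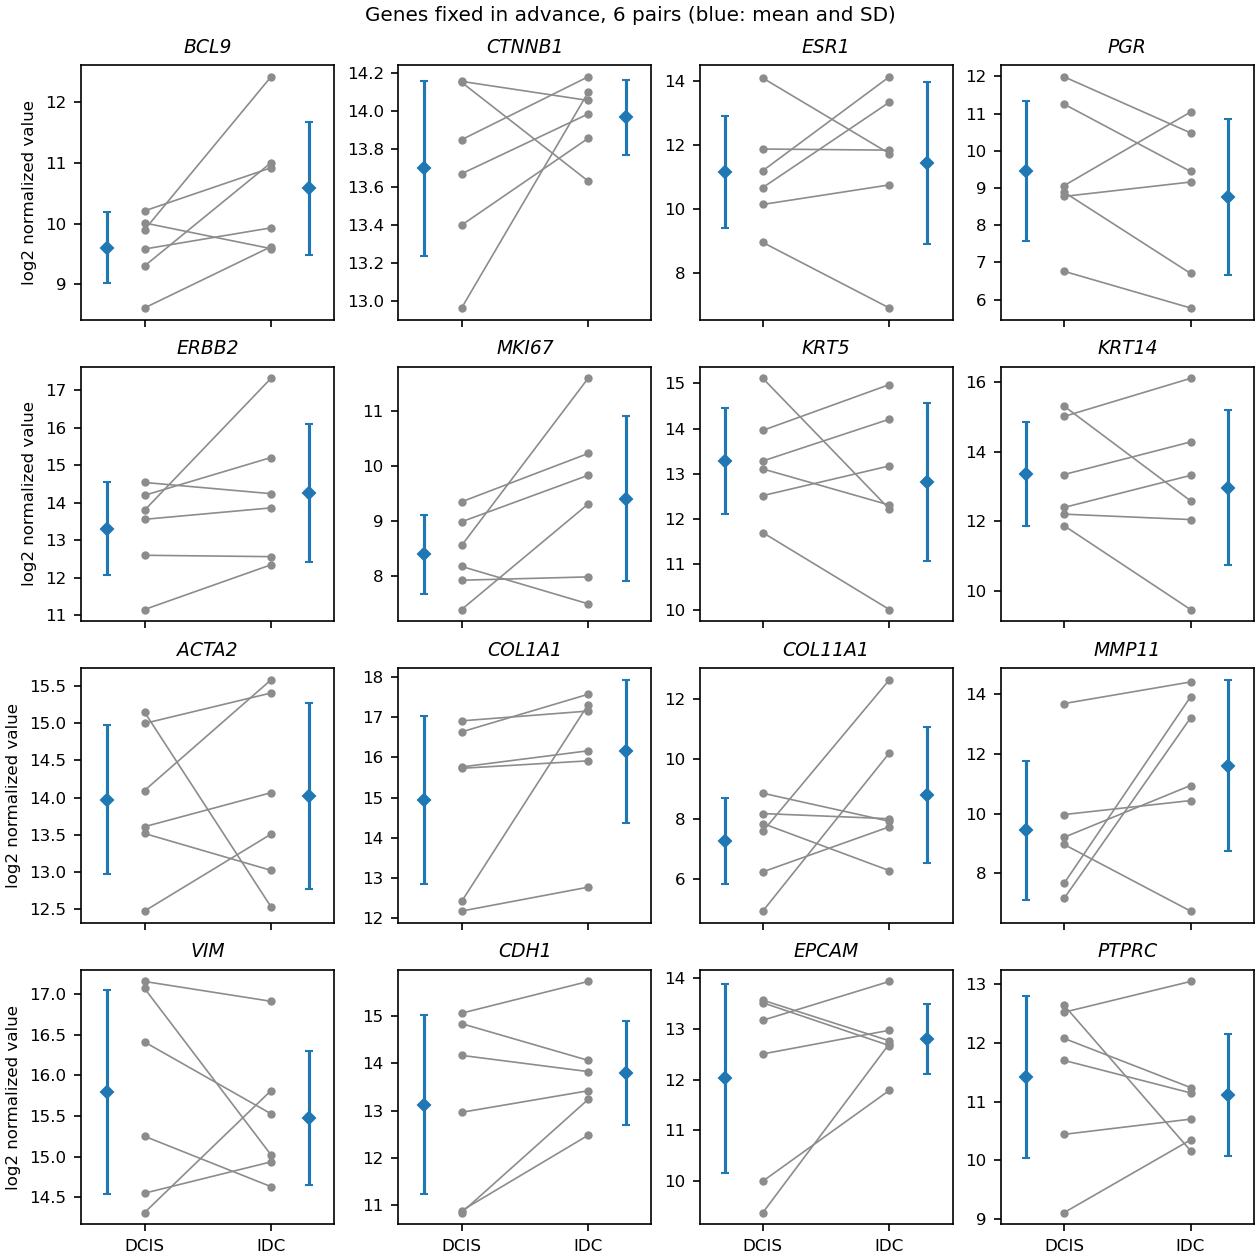
Normalized log2 value (y axis) of the 16 genes fixed in advance in DCIS and IDC (x axis), with 1 line per patient and the mean and SD of the 6 libraries of each type in blue. COL1A1 is higher in IDC in 6 of 6 pairs and BCL9, MKI67 and MMP11 in 5 of 6, and the lines of ESR1, KRT5 and KRT14 go both ways, 3 pairs each.

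Epithelial, proliferation and matrix genes were on average higher in IDC, and the sizes varied strongly between pairs. Of 25 luminal epithelial genes 24 were higher in IDC, 0 passed alone, and the list score differed by 0.85 ± 1.20 (log2, SD, n = 6) with 5 of 6 pairs higher. CLDN4, a tight junction protein, differed by 1.34 ± 0.45 (SE), KRT19 by 0.71 ± 0.25 and KRT8 by 1.20 ± 0.46. All 35 proliferation genes were higher, with a score difference of 0.73 ± 1.33 and 4 of 6 pairs higher. One DCIS library lay far above the other DCIS libraries in this score. The replication helicase genes MCM4 and MCM2 differed by 0.85 ± 0.35 and 0.82 ± 0.37, and by 0.47 and 0.45 at the lowest without one pair. Of 30 fibroblast and collagen matrix genes 28 were higher, with a score difference of 0.65 ± 1.20 in 4 of 6 pairs. POSTN differed by 0.96 ± 0.40 and BGN by 0.87 ± 0.47, and by 0.61 and 0.43 at the lowest without one pair. Of 22 genes of matrix proteases and their inhibitors 17 were higher (0.46 ± 0.72, 4 of 6 pairs), MMP14 by 0.47 ± 0.22. Immediate early genes, which also respond to tissue handling, were higher in 25 of 26 members (0.55 ± 0.95, 5 of 6 pairs), IER3 by 0.99 ± 0.27 and BTG2 by 1.02 ± 0.39. All 11 genes of the ERBB2 amplicon were higher (0.61 ± 1.07, 6 of 6 pairs), with one IDC library far above the others in the score. GRB7 differed by 0.96 ± 0.56, by 0.31 at the lowest without one pair, and by -0.15 with the luminal epithelial score as a covariate. Of 23 cell junction genes 17 were higher (0.39 ± 0.70, 4 of 6 pairs), JUP by 0.61 ± 0.18 and CGN by 1.25 ± 0.41. Of 20 genes of the unfolded protein response 17 were higher (0.23 ± 0.43, 5 of 6 pairs). XBP1 differed by 1.00 ± 0.48 and CALR by 0.40 ± 0.22, and by 0.47 and 0.22 at the lowest without one pair.

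These 8 lists passed camera with its preset correlation of 0.01, and none passed when the correlation was estimated from the data. The camera adjusted p was 1.4e-09 for luminal epithelial, 4.8e-09 for proliferation, 1.9e-06 for immediate early, 9.5e-06 for fibroblast and collagen matrix, 0.000459 for the ERBB2 amplicon, 0.0034 for cell junction, 0.00856 for matrix proteases and 0.0122 for the unfolded protein response. With an estimated correlation the adjusted p was 0.799 for each of them except the unfolded protein response, for which the adjusted p was 0.815. With the luminal epithelial score as a covariate and the preset correlation, proliferation (adjusted p = 0.49), cell junction (0.89), the ERBB2 amplicon (0.347) and the unfolded protein response (0.85) did not pass. The largest pair difference of each of these lists came from the pair with the largest luminal difference. That fit therefore cannot tell epithelial content from this pair. In the exact two-sided sign-flip test of the scores the ERBB2 amplicon had p = 0.03125, the smallest that 64 sign patterns allow, and adjusted over the 31 lists the lowest p was 0.969. Leaving out a pair ended the call of 6 of these 8 lists, with adjusted p of 0.087 for the ERBB2 amplicon without replicate 1, 0.15 for cell junction without 3, 0.154 for fibroblast and collagen matrix without 4, 0.059 for immediate early without 6, 0.067 and 0.352 for matrix proteases without 4 or 6, and 0.276 and 0.072 for the unfolded protein response without 1 or 2. Without replicate 1 the mean score difference was 0.41 for luminal epithelial, 0.34 for proliferation, 0.17 for the ERBB2 amplicon, 0.19 for cell junction and 0.079 for the unfolded protein response, without replicate 4 it was 0.18 for fibroblast and collagen matrix and 0.24 for matrix proteases, and without replicate 6 it was 0.18 for immediate early genes.

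Genes of the macrophage, myoepithelial, nerve and skin, and oxidative phosphorylation lists were on average lower in IDC. All 30 macrophage and dendritic cell genes were lower, with a score difference of -0.62 ± 1.17 (log2, SD, n = 6) and 5 of 6 pairs lower. MRC1, the mannose receptor, differed by -2.03 ± 0.67 (SE), MARCO, a scavenger receptor, by -2.90 ± 1.07, and AIF1 by -0.78 ± 0.36. Of 30 myoepithelial and basal genes 26 were lower (-0.40 ± 1.35, 3 of 6 pairs), EGFR by -0.96 ± 0.52 and SERPINB5 by -0.90 ± 0.54. Without one pair the difference shrank to as little as -0.45 for EGFR and -0.47 for SERPINB5. All 9 nerve and skin genes were lower (-0.62 ± 1.24, 3 of 6 pairs), among them MBP, a myelin protein, by -0.78 ± 0.28 in 6 of 6 pairs. One DCIS library lay far below the other DCIS libraries in the nerve and skin score. Of 25 genes of oxidative phosphorylation 17 were lower (-0.08 ± 0.14, 3 of 6 pairs), NDUFA4 by -0.36 ± 0.16 and COX7B by -0.43 ± 0.20. Mitochondrial transcripts, a separate list, went the other way on average, with 12 of 13 genes higher (0.14 ± 0.78, 2 of 6 pairs higher). The 4 lists lower in IDC passed camera with the preset correlation. The adjusted p was 1.9e-06 for macrophage, 0.00389 for myoepithelial, 0.0052 for nerve and skin and 0.0354 for oxidative phosphorylation. With the luminal epithelial score as a covariate all 4 calls ended (adjusted p = 0.89, 0.544, 0.719 and 0.191). The largest falls of the macrophage (-1.79) and nerve and skin (-2.53) scores came from the pair with the largest luminal rise. For these lists that fit cannot tell epithelial content from this pair. Leaving out a pair ended the call of the myoepithelial list (0.093 without replicate 1, 0.33 without 4), nerve and skin (0.074 without 1, 0.089 without 4) and oxidative phosphorylation (0.174 without 3, 0.298 without 4). With an estimated correlation the adjusted p was 0.939 for the myoepithelial list and 0.799 for each of the other lists. The macrophage difference was -0.38 without replicate 1 and -1.06 without replicate 6, and -0.0492 with the luminal epithelial score as a covariate. Nerve and skin was -0.24 without replicate 1, and without replicate 4 the myoepithelial difference was 0.035 and that of oxidative phosphorylation -0.034. In none of the 12 lists that passed did a member pass adjusted over the list alone or over all genes. The fry test, of whether a list moves one way on balance, passed 0 of 31 lists (lowest adjusted p = 0.874), and its test for change in either direction passed 0 (lowest adjusted p = 0.795).

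Other cell types showed no regular difference between the lesion types. The adipocyte score differed by -0.61 ± 4.34 (log2, SD, n = 6), with 3 pairs higher and 3 lower and a range over pairs from -6.13 to 5.79. T cell and NK cell genes differed by 0.0025 ± 0.96, with KLRD1, a natural killer cell receptor, at -1.21 ± 0.50 (SE) and FOXP3, the regulator of regulatory T cells, at 0.60 ± 0.27. B cell and plasma cell genes differed by -0.0051 ± 0.97, with MZB1, a plasma cell protein, at 0.85 ± 0.27 and CD79B at -0.43 ± 0.24. Endothelial genes differed by 0.09 ± 1.38, pericyte and smooth muscle genes by -0.37 ± 0.88 and blood cell genes by -0.34 ± 1.57 (SD). Antigen presentation and interferon genes differed by 0.12 ± 0.52, where the chemokines CXCL10 and CXCL11 were 0.84 and 0.83 higher, in 6 of 6 pairs each. None of these lists passed camera with the preset correlation, the lowest adjusted p among them being 0.0895 for the pericyte list. Several passed under alternatives, among them T cell and NK cell (camera adjusted p = 0.000142) and B cell and plasma cell (0.0214) without replicate 2. Without replicate 1 the endothelial (0.00282) and antigen presentation (8.1e-06) lists passed, and without replicate 6 the adipocyte (2.6e-06) and blood cell (0.000711) lists. The pericyte list passed with the stricter filter (0.0433), without replicate 3 (0.0155) and without replicate 6 (0.00719). Its score difference ranged from -0.60 to -0.14 without one pair.

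**Figure D3:**
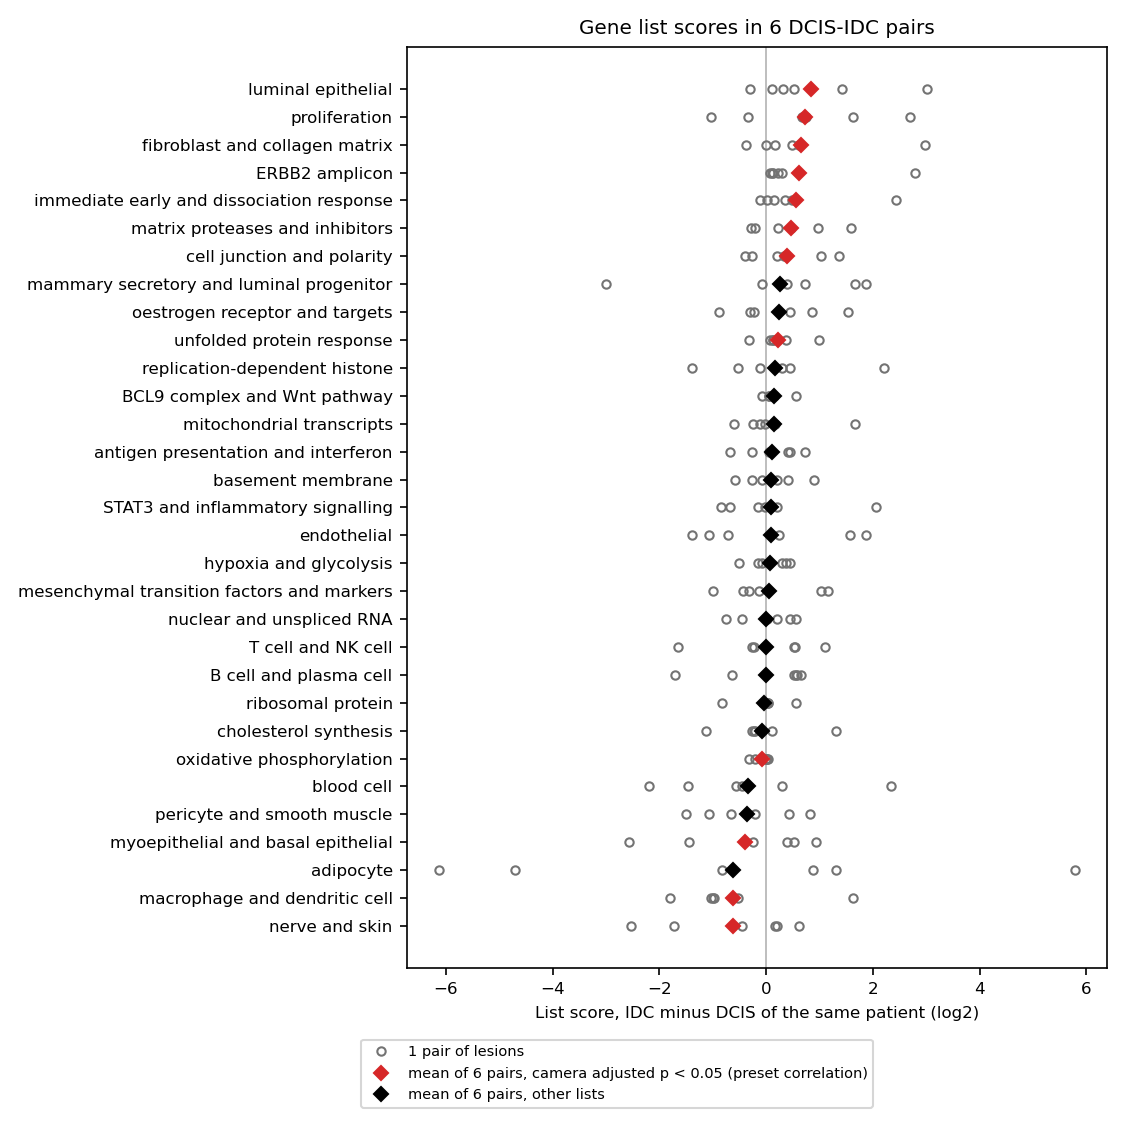
Difference of each gene list's mean log2 value between the IDC and the DCIS of one patient (x axis) for 31 lists (y axis), with 1 open circle per pair and the mean of 6 pairs as a diamond, red for the 12 lists that passed camera with the preset correlation. Most lists have pairs on both sides of 0, and the adipocyte list spans -6.13 to 5.79.

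Genes of the Wnt pathway and the oestrogen response were higher only in part. In the list of the BCL9 complex and Wnt pathway 18 of 33 genes were higher. The score differed by 0.15 ± 0.22 (log2, SD, n = 6), higher in 5 of 6 pairs, and by 0.063 to 0.19 without one pair. WNT7B, BCL9 and AXIN1 lay above 0 and PYGO1, a partner of BCL9, at -0.93 ± 0.38 (SE), and the camera adjusted p of the list was 0.219, or 0.048 without replicate 1. In the list of the oestrogen receptor and its targets 12 of 20 genes were higher (0.24 ± 0.88, SD), and AREG passed adjusted over the list alone (limma adjusted p = 0.0268, 0.774 over all genes) while the list did not pass camera (adjusted p = 0.26, or 0.0374 without replicate 6). Among its members TFF1 was 1.06 ± 0.52 higher and BCL2 -0.65 ± 0.32 (SE).

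The remaining lists did not pass camera with all 6 pairs, with differences that were small against their SD over the pairs. The mean differences were 0.27 ± 1.76 for mammary secretory and luminal progenitor genes, 0.10 ± 0.52 for basement membrane, 0.07 ± 0.37 for hypoxia and glycolysis, 0.05 ± 0.86 for mesenchymal transition genes and 0.09 ± 1.04 for STAT3 and inflammatory signalling (SD, n = 6). They were -0.07 ± 0.79 for cholesterol synthesis, -0.04 ± 0.44 for ribosomal proteins and 0.16 ± 1.20 for replication-dependent histones. Lists that reflect RNA quality or content differed by 0.14 ± 0.78 for mitochondrial transcripts and 0.0072 ± 0.51 for nuclear and unspliced RNA. Calls came and went with single pairs: mammary secretory genes passed without replicate 4 (adjusted p = 5.2e-06), cholesterol synthesis (8.1e-06) and basement membrane (0.0153) without replicate 1, and STAT3 signalling, lower in IDC, without replicate 6 (0.0314), while ribosomal proteins and histones passed in opposite directions when different pairs were left out.

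The authors' deposited table gave a signed fold and a p from a test named EDGE for each gene. Over the tested genes 294 had a p under 0.05 in the authors' deposited table, 231 with a positive and 63 with a negative fold, and after Benjamini-Hochberg adjustment over the tested genes the lowest of them was 1. Of these genes 93 also had an unadjusted limma p under 0.05, where independent lists of these sizes share 13, and both tests read the same libraries. For BCL9 the authors' deposited table gave a fold of 2.41 and p = 0.0146, for COL11A1 8.02 and p = 0.00236, for ERBB2 3.31 and p = 0.0212 and for MKI67 2.84 and p = 0.0176. For KRT14 the fold in the authors' deposited table was 1.70, in favour of IDC, while the mean of the normalized log2 values was lower in IDC by -0.39. Such opposed signs occurred in 2373 tested genes (15.3%).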

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

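Tests of the macrophage and luminal lists and of fat content were chosen after the results were seen, and the other tests before. In 9 of 138 groups of 6 libraries 1 library lay far from the others, where chance gives about 1 in 20, or 6.9. In each case the ratio of the gap to the range exceeded Dixon's 95% critical value. SUSD2 had one library far above the others in DCIS (ratio 0.767) and in IDC (0.673). The highest library stood apart for the proliferation score in DCIS (0.715), and in IDC for PTPRC (0.627), the endothelial score (0.667) and the ERBB2 amplicon score (0.814). The lowest library stood apart for the mitochondrial transcripts score (0.808) and the nerve and skin score (0.66) in DCIS and for COL1A1 in IDC (0.655).

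The first pattern is the absence of passing genes beside 12 passing lists. Swapping the lesion labels within pairs gave 32 splits that keep every pair parted, and 0 genes passed in each, which decides nothing because all 32 must equal or exceed a real count of 0 (highest other split 0). Chance cannot be excluded for the other counts. The 701 genes at an unadjusted p under 0.05 were equalled or exceeded in 11 of 32 splits, with 2171 in the highest other split, several times the real count; what set that split apart was not tested, and 0 genes passed in it. The 12 lists passing camera with the preset correlation were equalled or exceeded in 31 of 32 splits, with 25 in the highest other split and a median of 17. The adipocyte score as a covariate lowered the residual SD of the median gene by 3.5% (from 0.438 to 0.423), and 0 genes passed. Fat content that differs within pairs thus took up little of the median gene's spread. The median gene does not speak for genes that follow fat, and no other covariate was measured this way for comparison. For those genes the explanation stays open.

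The second pattern is the lower macrophage score (-0.616) and the higher luminal score (0.846) in IDC. A lower share of all non-epithelial cells would lower the other 6 stromal and immune lists (T and NK cell, B and plasma cell, endothelial, pericyte, fibroblast and adipocyte) too. Their mean was -0.0409 ± 1.24 (log2, SD, n = 6) over members that went both ways, fibroblast at 0.65 ± 1.20 (28 of 30 genes higher, against the explanation but within the spread of the pairs) and adipocyte at -0.61 ± 4.34, and the macrophage score lay below it in 5 of 6 pairs (exact two-sided sign-flip p = 0.0625), which leaves the explanation open. With the luminal score as a covariate the macrophage difference went from -0.616 ± 0.478 to -0.0492 ± 0.489 (log2, SE). Its camera call ended (adjusted p = 0.89) because the estimate moved to near 0 while its SE hardly changed. The largest luminal rise (3.01) and the largest macrophage fall (-1.79) came from the same pair. That fit therefore cannot tell epithelial content from this pair. The differences of both lists had a Pearson r of -0.689 over the 6 pairs (exact permutation p = 0.179). Spearman rho was -0.714 (exact permutation p = 0.136). Without the 2 pairs farthest from the median in the luminal difference, r was -0.787. The only pair in which the macrophage score rose (by 1.62) stayed in. This value therefore does not show that r holds without extreme pairs. A trade between epithelial and macrophage RNA in the piece sampled may contribute but was not decided by 6 pairs. A change with invasion itself stays open and untested.

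The third pattern is the opposed sign of the deposited fold and the normalized difference in 2373 genes. Averaging before the logarithm could account for part: with the normalized values averaged on the linear scale 39.4% of these genes matched in sign. The other 60.6% stayed opposed. In the 9825 genes whose reads were recovered, the deposited fold was made from reads not normalized between libraries, since it equalled the ratio of mean reads in 100%. Reads were recovered only up to a value of 7.26. For opposed genes above that value, KRT14 among them, the fold was not checked against reads. KRT14 was among the genes that matched in sign once the normalized values were averaged on the linear scale.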

How the results depend on the processing

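The luminal and adipocyte covariates and cyclic loess were chosen after seeing the data. The count of genes passing limma was 0 under every alternative run. At an unadjusted p under 0.05 the 701 genes became 125 with no replicate block (113 shared), 1160 with no filter, 248 with the luminal epithelial score as a covariate and 334 to 1540 without one pair. The low end was without replicate 1, the high end without replicate 6, and 465 and 461 were counted without replicates 4 and 5. The 12 lists passing camera were the same 12 with no replicate block, 0 with an estimated correlation, 11 with the luminal score as a covariate (3 shared), and 11 to 15 without one pair. With the luminal score as a covariate only the fibroblast, immediate early and matrix protease lists of the 12 still passed; the macrophage list lost the call (adjusted p = 0.89, camera direction turned against other genes, score difference still -0.0492), the camera directions of the ERBB2 amplicon (0.347) and the unfolded protein response (0.85) turned lower, and proliferation (0.49), cell junction (0.89), myoepithelial (0.544), nerve and skin (0.719), oxidative phosphorylation (0.191) and the luminal list itself (0.85) lost the call. For the luminal list this loss carries no information, because the covariate is the mean of that list's own genes. The pair with the largest luminal difference also had the largest macrophage, proliferation, cell junction, ERBB2 amplicon, and unfolded protein response differences. The same held for nerve and skin. For these lists the lost calls cannot tell epithelial content from this pair. Oxidative phosphorylation also lost its call with the adipocyte score (0.0541). Luminal epithelial, proliferation and macrophage lists passed without each pair in turn. These fits used the preset correlation, with which 31 of 32 label splits called as many lists or more. Passing them therefore does not exclude chance. The other lists lost the call as follows: cell junction without replicate 3 (camera adjusted p = 0.15), the ERBB2 amplicon without 1 (0.087), fibroblast and collagen matrix without 4 (0.154), immediate early without 6 (0.059), matrix proteases without 4 or 6 (0.067 and 0.352), myoepithelial without 1 or 4 (0.093 and 0.33, the latter with the direction turned), nerve and skin without 1 or 4 (0.074 and 0.089), oxidative phosphorylation without 3 or 4 (0.174 and 0.298), and the unfolded protein response without 1 or 2 (0.276 and 0.072). Lists outside the 12 gained a call too. Among them were pericyte with the stricter filter (0.0433), without 3 (0.0155) and without 6 (0.00719), and T cell and NK cell without 2 (0.000142). Others were adipocyte, lower without 6 (2.6e-06) but higher with the luminal score (0.027), and endothelial (0.00282) and antigen presentation (8.1e-06) without 1. With the luminal score antigen presentation (1.0e-11), endothelial (3.4e-06), mesenchymal transition (0.00038), STAT3 signalling (0.00058) and basement membrane (0.0011) gained a call as higher. In the same fit cholesterol synthesis (2.9e-07) and histones (0.00094) gained a call as lower. Ribosomal proteins were lower without 3 (0.0101) and higher without 4 (0.0147), and histones lower without 1 (0.0373) and higher without 4 (0.0106). The list score test found 1 of 31 lists at an unadjusted exact p under 0.05, none after adjustment, and 0 at the unadjusted p with no filter, with medians and without any one pair, where 5 pairs cannot give a p under 0.0625. The mean correlation within patients stayed between 0.333 and 0.505 over the scalings, filters, pseudocounts, gene set and rank method tried for it, and from 0.337 to 0.491 without one pair, in each the highest of the pairings.

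Of 1690 gene values under alternatives 28 changed sign, in 14 of 100 genes. With array weights ESR1 was -0.11, KRT5 0.11 and KRT14 0.28. With the adipocyte score as a covariate ACTA2 was -0.015. With the luminal score as a covariate the values were THRSP 0.12, ERBB2 -0.0064, GRB7 -0.15, CDK12 -0.018, PMP22 0.054, CTNNB1 -0.073, ESR1 -0.83, KRT14 0.27, ACTA2 -0.35, VIM 0.32, CDH1 -0.080, EPCAM -0.23 and PTPRC 0.0066. Without one pair ESR1 ranged from -0.23 to 0.82, KRT14 from -0.69 to 0.078, KRT5 from -0.76 to 0.018, ACTA2 from -0.24 to 0.58, VIM from -0.68 to 0.028 and PTPRC from -0.62 to 0.13. Of 403 list scores 35 changed sign, and 13 of 31 lists never did. T cell and NK cell was -0.037 with quantile normalization over the tested genes, mammary secretory -0.046 with no filter, and B cell and plasma cell 0.11 with the stricter filter and 0.030 with cyclic loess. With medians basement membrane was -0.088, cholesterol synthesis 0.0095, hypoxia and glycolysis -0.12 and mesenchymal transition -0.0075. Without one pair the ranges were -0.14 to 0.34 for B cell and plasma cell, -0.30 to 0.28 for STAT3 signalling, -0.22 to 0.33 for T cell and NK cell, -1.89 to 0.49 for adipocyte, -0.0068 to 0.28 for antigen presentation, -0.061 to 0.23 for basement membrane, -0.88 to 0.030 for blood cell, -0.34 to 0.14 for cholesterol synthesis, -0.27 to 0.38 for endothelial, -0.0078 to 0.18 for hypoxia, -0.054 to 0.92 for mammary secretory, -0.17 to 0.26 for mesenchymal transition, -0.16 to 0.29 for mitochondrial transcripts, -0.67 to 0.035 for myoepithelial, -0.10 to 0.16 for nuclear RNA, -0.018 to 0.47 for oestrogen receptor targets, -0.25 to 0.47 for histones and -0.16 to 0.11 for ribosomal proteins. The cause was not tested for any of these. Count tests (DESeq2 and voom) were not run, since the table holds no counts, and low genes in the shallower libraries are limited by depth.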

Other observations

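The lists differed in how much they varied between the lesions of one patient. The SD over pairs of the score difference was highest for 3 lists, 4.34 for adipocytes, 1.76 for mammary secretory and luminal progenitor genes and 1.57 for blood cell genes (log2, n = 6), against 0.14 for oxidative phosphorylation and 0.22 for the BCL9 complex and Wnt pathway. Within the mammary secretory list SCGB2A2, mammaglobin, was 1.60 ± 0.50 higher in IDC (SE) and PROM1 1.41 ± 0.61 higher, each in 5 of 6 pairs, without passing (limma adjusted p = 0.774 for SCGB2A2). In the hypoxia list the glucose transporter gene SLC2A1 was 0.90 ± 0.35 higher in 5 of 6 pairs, also without passing.

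Genes of a list varied together between libraries beyond what patient and lesion type account for in the fit. This correlation between genes of a list, estimated by camera, had a median of 0.542 over the 31 lists and reached 0.943 for adipocyte genes, where the preset was 0.01. It was 0.0104 for the BCL9 complex and Wnt pathway.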
